A study of Mus musculus with 24 samples.

How the data were processed

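RNA from mice was measured on 24 single-colour expression arrays, 3 in each of 8 groups, wild type and mutant at the codes V, dp12, dp18 and Lac10. Total RNA was extracted with Trizol and labelled as biotin cRNA, per the labels' protocols. The deposited values are log2 expression values from RMA (robust multi-array average), per the submitters' processing notes, with the version not stated. RMA corrects background, sets all arrays to a common distribution of probe intensities and summarises probes, so a shift shared by most genes cannot be seen in its output. The authors' between-array normalization was kept. Values ran from 1.98 to 13.5 with none missing, array medians from 5.31 to 5.62 and array SDs from 1.65 to 1.99. For arrays, their number limits the precision.

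The labels do not name the tissue or the allele, and their treatment text describes an RNA pull-down with a tagged PAB-1 protein from named cells and an amplification kit, which differs from the total RNA named elsewhere in the same labels and is not settled here. The design text gives V as 0 and the numbers of the other codes as months, while dp and Lac are read here as day of pregnancy and of lactation. Groups were taken from the titles and the stage label. Wild-type replicate numbers come from the titles, and mutant arrays were numbered in accession order, so no pairing between genotypes was used. No genome build is given in the sources used here, and no coordinates are printed.

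Of 41345 probe sets, 23521 carry 1 gene symbol in the platform annotation, 1814 several and 16010 none, and only the first kind was named. They hold 22180 genes, of which 1082 have more than 1 probe set and are represented by the probe set of highest mean, with another of opposite sign mentioned beside the gene. A gene was kept where at least 3 arrays lay above that array's median, which left 15234 and removed 6946. No column of other samples was used.

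Each gene was fitted with limma (version 3.58.1 in R 4.3.3) on all 24 arrays with 1 mean per group, which left 16 residual degrees of freedom beside 4.35 prior ones. Moderated statistics with Benjamini-Hochberg adjustment and a threshold of 0.05 tested genotype at each of the 4 stages, genotype averaged over stages, equality of the 4 genotype differences by a moderated F test, and each stage step within a genotype. The difference between genotypes in each step was tested as a contrast. For 27 gene lists written before the data were examined, camera was run with a preset correlation of 0.01, adjusted over the lists in a contrast, with an estimated correlation and fry beside it. With the preset, 6, 12, 12 and 10 lists were called for genotype at V, dp12, dp18 and Lac10 and 12 on average. With an estimated correlation the calls that held were 2 in the mutant step from V to dp12, mitosis and hormone-sensing luminal epithelium, and 0 elsewhere. The share of members measured was lowest for brown adipocyte (9 of 15), plasma cell (7 of 11), skeletal muscle (13 of 23), keratinocyte and hair follicle (10 of 24), peripheral nerve (7 of 14) and housekeeping (19 of 24). In wild type from V to dp12 these 6 lists had medians of 0.66, 0.26, -0.69, -0.13, 0.09 and 0.22, of which skeletal muscle alone was called (-0.10 and not called without wild-type virgin replicate 2, -1.09 without replicate 1); with housekeeping centring the plasma cell, nerve and housekeeping medians were -0.19, -0.36 and -0.24.

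Centring each array on the median of the housekeeping list moved the median of all genes by -0.15, -0.26 and 0.46 for genotype at V, dp18 and Lac10. For the steps V to dp12, dp12 to dp18 and dp18 to Lac10 it moved by -0.45, 0.40 and -0.30 in wild type and by -0.40, 0.24 and 0.42 in mutants. Centring on the array median moved it by -0.10 from dp12 to dp18 in wild type and by less in the other comparisons. The camera test sets a list against all other genes, and centring shifts both alike. A list call that is kept with centring is therefore only a weak check on scaling, and its direction can differ from that of the centred median.

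The genes named were fixed by a rule before the data were examined. For each genotype comparison it takes the 10 largest rises and falls among genes past the threshold whose groups do not overlap, for the average those with the same sign at all 4 stages, or the 10 smallest p values where fewer pass. It takes the 6 largest rises and falls per stage step, up to 4 members of each list that passed or the 2 largest as values, and Brca1, Esr1, Pgr, Wee1, Mcm2 and Cdkn1a throughout. The comparisons, the tests and most alternatives were also chosen before the data were examined. The alternatives covered probe set choice, the filter, both centrings, a variance trend, array weights, the arrays of the compared groups alone, body weight from the titles, the wild-type number as a block, and each array left out. Others, chosen after seeing the data, left out 3 arrays with a median correlation under 0.9, 7 under 0.94, or 2 whose nonagouti level goes against the label, used that correlation as a covariate, or kept the 22 arrays with a weight, or left out each array in turn for the lists of the stage steps.

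The analysis was tested on simulated data with the real design, 10 runs of 200 changed genes among 15234. Of genes changed by a log2 value of 1, 39.9% were recovered for genotype at V and 34.3% at Lac10, and of those changed by 2, 88.7% and 85.1%. For the average, 89.2% and 98.5% were recovered. With no change at all, the preset camera test called a median of 9 of the 27 lists for genotype at V and 9.5 at Lac10, so its calls alone do not set a list apart. With no change, 1 run of 10 called genes at Lac10 (2917), 1 on average (3340), 2 at dp18 (highest 675) and 1 each from dp18 to Lac10 in wild type (1320) and mutants (456). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.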

Results

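Gene expression was measured on 24 single-colour arrays of mouse RNA, 12 from wild-type and 12 from mutant animals of a mixed FVB, 129SVEV and Black Swiss background. The subject of the series is BRCA1, a tumour suppressor that acts in homologous recombination repair, together with replication forks, mitosis and oestrogen signalling in pregnancy. The arrays fell into 8 groups of 3, each genotype at the stages coded V, dp12, dp18 and Lac10, read here as virgin, pregnancy and lactation. The design text gives the numbers of these codes as months, so the time that a code stands for is not settled and the codes are printed as labelled. The labels name neither the tissue nor the mutated allele. Of 22180 genes with a single symbol, 15234 were tested. The values are log2 intensities from 1.98 to 13.5, with array medians between 5.31 and 5.62. Differences below are log2 values, mutant minus wild type or later minus earlier stage, with the standard error (SE) of the fit. The number of arrays limits the precision, with a median SE of 0.3 for a single comparison. The titles number the arrays of each group apart and give most of them a body weight of their own, yet no label states that each holds a separate animal, so the p-values measure the spread between these arrays.

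The arrays differed in how well they resembled the rest. The median correlation of an array with the other 23 reached 0.968 and was lowest in mutant Lac10 replicate 2 at 0.799, wild-type dp18 replicate 1 at 0.837 and mutant dp18 replicate 1 at 0.863. The 3 wild-type virgin arrays lay at 0.910, 0.920 and 0.907, while the mutant virgin arrays lay at 0.964, 0.953 and 0.964. Every array of both dp12 groups was at 0.96 or above. Comparisons that involve the wild-type virgin, dp18 or mutant Lac10 groups set arrays of unequal resemblance against each other.

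**Figure D1:**
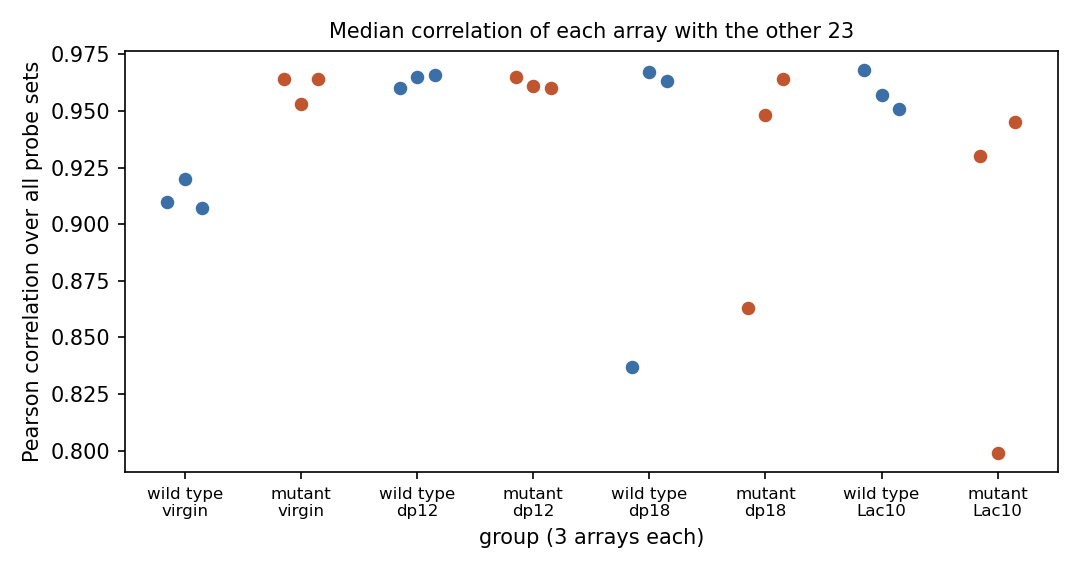
Median Pearson correlation over all probe sets of each array with the other 23 (vertical axis, no unit), 3 points per group, wild type blue and mutant orange. The lowest points are mutant Lac10 replicate 2 at 0.799 and wild-type dp18 replicate 1 at 0.837, and the 3 wild-type virgin arrays lie between 0.907 and 0.920.

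Brca1 was highest at dp12 in both genotypes and did not pass as different between them at any stage. In wild type its mean level was 5.04 ± 0.32 (SD, n = 3) in virgins, 6.10 ± 0.34 at dp12, 5.49 ± 0.18 at dp18 and 5.19 ± 0.48 at Lac10. In mutants it was 4.89 ± 0.58, 6.56 ± 0.21, 5.65 ± 0.32 and 5.06 ± 0.46. The genotype difference was -0.14, 0.45, 0.15 and -0.14 at the 4 stages, with an SE of 0.31 and no adjusted p below 0.816 (limma). The Brca1 probe set may lie outside a deleted part of the gene, and the allele is not in the labels, so these levels check nothing about the genotype. Between virgin and dp12 Brca1 rose by 1.07 (SE 0.31, adjusted p = 0.0445) in wild type and by 1.66 (SE 0.31, adjusted p = 0.00244) in mutants.

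Of the other genes followed at every stage, Pgr, which encodes the progesterone receptor, passed as higher in mutant virgins and passed at no later stage. Its level was 8.28 ± 0.24 in mutant and 6.48 ± 0.81 in wild-type virgins (n = 3), and 5.64 ± 0.19 against 6.05 ± 0.42 at dp12. Esr1, the oestrogen receptor alpha gene, was at 8.20 ± 0.81 against 7.37 ± 0.12 in virgins (adjusted p = 0.32). Wee1, the kinase that holds CDK1 inactive, differed by 0.91, -0.17, -0.60 and -1.35 across the 4 stages, and the last of these had an adjusted p of 0.263. Mcm2, a subunit of the replicative helicase, differed by 0.07, 0.40, 0.11 and -0.33. Cdkn1a, the p53 target that encodes p21, differed by 0.37, -0.05, -0.01 and -0.98 (adjusted p at Lac10 = 0.167). No Esr1, Wee1, Mcm2 or Cdkn1a difference between genotypes passed in limma.

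Between virgin and dp12 in wild type, 983 genes changed, 901 of them higher and 82 lower (limma, adjusted p under 0.05). Of 43 measured mitosis genes 40 rose, among them Mki67, a marker of cycling cells, by 3.00 (SE 0.54, adjusted p = 0.00924), the mitotic cyclin gene Ccnb2 by 2.79, Ect2, needed for cytokinesis, by 2.74 and the spindle motor gene Kif11 by 2.68. Of 57 genes of DNA replication 29 rose, such as Rrm1, a subunit of ribonucleotide reductase, by 1.77, the helicase gene Mcm6 by 1.70 and the primase gene Prim1 by 1.65. Pole rose by 1.89 on its brightest probe set, with another of opposite sign. Adjusted over the list alone, 43 mitosis and 48 replication genes rose. Among 36 genes of homologous recombination and Fanconi repair 14 rose, 21 adjusted over the list alone, with the checkpoint kinase gene Chek2 up by 1.92, Blm by 1.37, Atm by 1.37 and Rad18 by 1.36. The medians of these 3 lists were 2.00, 1.10 and 0.81 (camera with its preset correlation, adjusted p = 2.36e-25, 9.49e-14 and 1.34e-07), and the adjusted p = 0.553 with an estimated correlation for each of them. Centred on the housekeeping list, the replication and repair medians were 0.65 and 0.36, still called.

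Genes of milk secretion and lipid synthesis rose in the same step. In wild type 9 of 30 milk and secretory genes rose, 14 adjusted over the list alone. They included Olah, which ends fatty acid synthesis at medium chain lengths, by 4.85 (SE 0.65, adjusted p = 0.00447), Glycam1 by 3.44, the phosphate transporter gene Slc34a2 by 3.05 and Lao1 by 2.91. Of 39 lipid synthesis genes 11 rose (17 adjusted over the list alone), such as Lpin1 by 2.43, the fatty acid synthase gene Fasn by 2.29, Thrsp by 2.11 and Hmgcs1 by 1.64. Of 43 genes of mitochondrial oxidative phosphorylation 4 rose, 16 adjusted over the list alone, among them Ndufs1 by 1.34 and Uqcrc2 by 0.92. These 3 lists had medians of 1.12, 0.85 and 0.56 and preset adjusted p values of 0.000595, 1.61e-05 and 2.7e-05. With an estimated correlation the adjusted p = 0.607 for milk and 0.612 for both others. These 3 medians were, with housekeeping centring, 0.67, 0.40 and 0.11, still called. Fam20a, a secretory pathway pseudokinase gene, rose by 3.10.

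Of 12 hormone-sensing luminal genes 3 fell in wild type at dp12, the pioneer factor gene Foxa1 at -1.68, Prom1 at -1.18 and Cited1 at -0.82, and none rose (list median -0.36, adjusted p = 0.0154, adjusted p = 0.553 with an estimated correlation; median -0.17 without wild-type virgin replicate 3). Adjusted over the list alone, 3 fell and 3 rose. Among 17 basal and myoepithelial genes 5 rose, 8 adjusted over the list alone, namely the oxytocin receptor gene Oxtr by 1.74, the contractile genes Cnn1 by 1.34, Myh11 by 1.30 and Actg2 by 1.11, and Mylk by 0.94, named after its value was seen. The largest falls were in Gm26504 at -4.13, the vomeronasal receptor gene Vmn1r14 at -3.50, 9530057J20Rik at -3.39, Btbd35f16 at -3.17, the olfactory receptor gene Olfr1141 at -2.52 and the fibrinogen chain gene Fgb at -2.43. T and B lymphocyte genes were lower at dp12 in 27 of 28 cases with a median of -0.61 (adjusted p = 1.42e-06, and adjusted p = 0.612 with an estimated correlation), and of them the chemokine gene Cxcl13 fell by 1.97 over all genes, with none passing adjusted over the list alone. That median was 0.09 and not called without wild-type virgin replicate 2, and -0.96 without replicate 1. With housekeeping centring the hormone-sensing and lymphocyte medians were -0.81 and -1.06, both called. The count of 983 rests on single arrays: it was 0 without wild-type virgin replicate 2, 18 without virgin replicate 3, and 4, 146 and 273 without dp12 replicates 1, 2 and 3. Without the 3 arrays of lowest correlation it was 6271, and with each array centred on the housekeeping list 131, of which 91 were higher and 40 lower.

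In mutants the same step changed 677 genes, 460 higher and 217 lower. Of 43 mitosis genes 41 rose, with Ect2 up by 3.69 (SE 0.64, adjusted p = 0.00156), Mki67 by 3.37, Ccnb2 by 3.15 and Kif11 by 3.10. The list median was 2.42 and the call held with an estimated correlation (adjusted p = 0.0462; 3.95e-59 with the preset). Of 57 replication genes 31 rose, among them Rrm2 by 2.34, the flap endonuclease gene Fen1 by 2.17, Ticrr, needed for origin firing, by 2.14 and, with a probe set of opposite sign, Pole by 2.59. Of 36 repair genes 17 rose, such as Chek2 by 2.36, the exonuclease gene Exo1 by 1.85, H2ax by 1.53 and Blm by 1.49. Adjusted over the list alone, 42 mitosis, 48 replication and 18 repair genes rose. The replication and repair lists had medians of 1.13 and 0.61, which were 0.74 and 0.215 with housekeeping centring and still called, preset adjusted p values of 3.58e-33 and 1.56e-14, and adjusted p = 0.137 and 0.141 with an estimated correlation. Mcm2 also rose, by 1.66 (SE 0.46, adjusted p = 0.0437).

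Hormone receptor genes fell in mutants over this step. Of 12 hormone-sensing luminal genes 6 fell, 7 adjusted over the list alone, with Foxa1 at -2.80, Pgr at -2.64 (SE 0.32, adjusted p = 0.000117), Prom1 at -2.44 and Esr1 at -1.52 (SE 0.41, adjusted p = 0.0357). The list median was -0.83, and its call held with an estimated correlation (adjusted p = 0.0109). Of 27 oestrogen-responsive genes 5 fell, 5 also adjusted over the list alone, adding Stc2 at -1.74 and Greb1 at -0.76, the latter named after its value was seen. That list had a median of -0.28, which was -0.67 with housekeeping centring and still called, a preset adjusted p of 0.000482 and an adjusted p = 0.137 with an estimated correlation. Of 30 milk and secretory genes 7 rose, led by Olah by 5.96, the whey acidic protein gene Wap by 4.20, Lao1 by 3.84 and Glycam1 by 3.36, while the water channel gene Aqp5, named after its value was seen, fell by 1.92. Of 39 lipid synthesis genes 9 rose, among them Thrsp by 2.63, Fasn by 2.49, Acaca by 2.05 and Fads1 by 1.75, and of 43 oxidative phosphorylation genes 10 rose, such as Cox7c by 1.39 and Ndufa5 by 1.05. Adjusted over the list alone 12, 17 and 31 members of these 3 lists rose. Their medians were 0.86, 0.86 and 0.74, and 0.46, 0.46 and 0.34 with housekeeping centring, still called. Their preset adjusted p values were 8.65e-07, 8.11e-12 and 4.51e-18, and adjusted p = 0.193, 0.267 and 0.137 with an estimated correlation.

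Other large changes in mutants were rises of Gldc, of the glycine cleavage system, by 3.98 and of the peptide hormone gene Apln by 3.71, and falls of Fgb at -4.15, Cxcl15 at -3.69, the cysteine dioxygenase gene Cdo1 at -3.14, the cystine transporter gene Slc7a11 at -3.06 and Cyp3a57 at -2.98. The count of 677 was 262 without mutant virgin replicate 2, 423 without virgin replicate 3, and 430, 281 and 284 without dp12 replicates 1, 2 and 3. It was 1605 without the 3 arrays of lowest correlation, and 1623 with housekeeping centring, where the split turned to 272 higher and 1351 lower. Of the genes that rose, 294 did so in both genotypes, where independent lists of 901 and 460 genes would share 27.2, and 28 fell in both, where independent lists would share 1.2. The wild-type and mutant steps use different arrays but the same spread for each gene. Genes of small spread can therefore pass in both, so the shares of independent lists are only a rough reference.

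**Figure D2:**
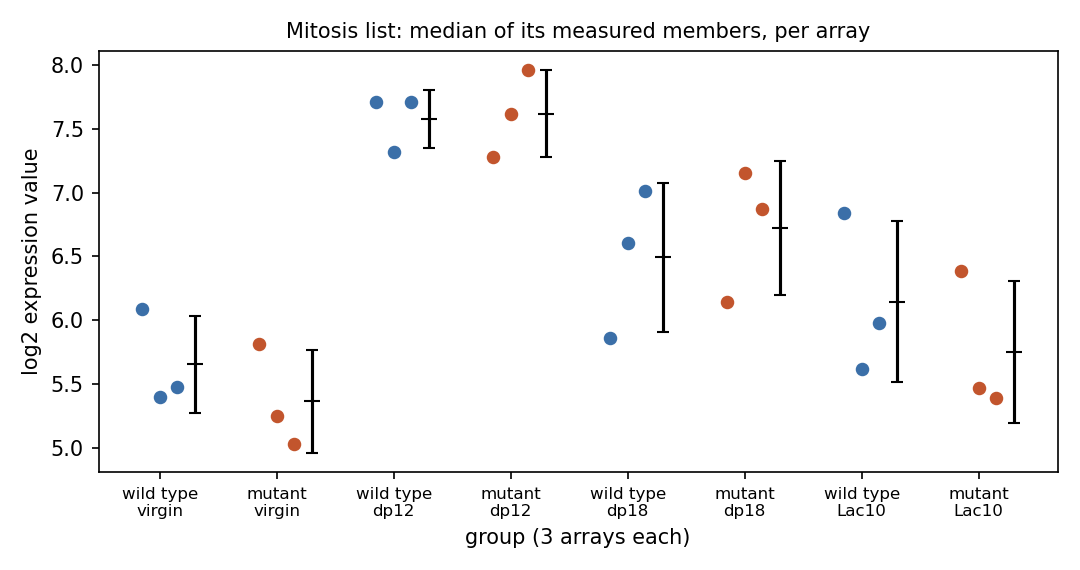
Median log2 expression value of the 43 measured mitosis genes on each array (vertical axis), 3 points per group, with the group mean ± SD in black beside them. Both dp12 groups lie between 7.28 and 7.96, above every virgin array, the highest of which is at 6.09.

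After dp12 the division genes were lower again in wild type. At dp18 all 43 mitosis genes lay below their dp12 level, with a list median of -1.04, and so did all 57 replication genes, with a median of -0.76 (preset adjusted p = 7.98e-17 and 2.44e-14, adjusted p = 0.608 with an estimated correlation for both). No single gene passed over all genes, whereas 28 mitosis and 21 replication genes fell adjusted over the list alone, with Cdc20 at -1.42 and Mcm5 at -1.24. Milk genes had a median of 0.26 (adjusted p = 0.00303, and adjusted p = 0.608 with an estimated correlation), with Wap at 2.36 (SE 0.59, adjusted p = 0.484) and the alpha-lactalbumin gene Lalba at 2.09. Basal and myoepithelial genes were higher in 16 of 17 cases, with a median of 0.50 (adjusted p = 8.65e-11, and adjusted p = 0.244 with an estimated correlation). The replication median was -0.45 without wild-type dp18 replicate 1, and the milk median 0.10 without dp12 replicate 3 and 0.16 without dp18 replicate 2, all still called with the preset. With housekeeping centring the mitosis, replication and basal medians were -0.64, -0.36 and 0.90, still called, and the milk median 0.65, not called. The limma count was 0, with 1476 genes at an unadjusted p under 0.05 and 2751 called with array weights. It was 1 without wild-type dp18 replicate 2.

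From dp18 to Lac10 in wild type all 39 lipid synthesis genes were higher, with a median of 1.00, and 25 rose adjusted over the list alone, such as the sterol regulator gene Insig1 at 1.96 and the citrate carrier gene Slc25a1 at 1.73 (preset adjusted p = 3.37e-21, adjusted p = 0.5 with an estimated correlation). Milk genes had a median of 0.75, and 6 rose adjusted over the list alone, with the casein gene Csn1s2b at 3.41 and Slc34a2 at 2.90 (adjusted p = 4.15e-05, and adjusted p = 0.5 with an estimated correlation). All 23 interferon-stimulated genes were higher, with a median of 0.84, and 11 rose adjusted over the list alone, among the list Oas2 at 1.67 (adjusted p = 3.24e-10, and adjusted p = 0.5 with an estimated correlation). Macrophage and neutrophil genes were higher in 22 of 25 cases in that step, with a median of 0.76 (adjusted p = 0.00251, and adjusted p = 0.802 with an estimated correlation), which was 0.35 without wild-type dp18 replicate 1 and 0.64, not called, without the array labelled wild-type Lac10 replicate 1. T and B lymphocyte and endothelial genes had medians of 0.48 and 0.51 and were not called; with housekeeping centring they were at 0.18 and 0.21 and called (adjusted p = 0.00188 and 0.00778). Mitosis genes had a median of -0.34 (adjusted p = 1.42e-07, and adjusted p = 0.802 with an estimated correlation), which was -0.69 and -0.12 without dp18 replicates 1 and 3, and -0.65 and -0.10 without the array labelled wild-type Lac10 replicate 1 and Lac10 replicate 2. Milk, interferon, macrophage and mitosis medians were 0.45, 0.54, 0.46 and -0.635 with housekeeping centring, all still called. No gene passed over all genes in limma, with 1219 at an unadjusted p under 0.05 and 3898 called with array weights. The count was 148 without the array labelled wild-type Lac10 replicate 1, and 149 without it and the array labelled mutant dp18 replicate 2.

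In mutants the later steps also gave no gene past the threshold by limma. From dp12 to dp18 all 43 mitosis genes and 56 of 57 replication genes were lower, with medians of -0.93 and -0.80 (preset adjusted p = 7.06e-12 and 1.66e-15, adjusted p = 0.411 with an estimated correlation for both), and 8 and 36 fell adjusted over the list alone, with Melk at -1.43 and Gins1 at -1.39. All 22 luminal epithelium genes were lower, with a median of -1.20, and 8 fell adjusted over the list alone, with Elf3 at -2.01 (adjusted p = 7.27e-07, and adjusted p = 0.42 with an estimated correlation). All 19 endothelial genes were higher, with a median of 0.94 and Kdr, a VEGF receptor gene, at 1.59, not passing (list adjusted p = 8.66e-10, and adjusted p = 0.411 with an estimated correlation). Without the array labelled mutant dp18 replicate 2 the endothelial median was 0.31 and the luminal one -0.68, and without mutant dp18 replicate 1 the mitosis and replication medians were -0.62 and -0.53. At an unadjusted p under 0.05 there were 2082 genes, with array weights 1, and 25 without mutant dp18 replicate 3. From dp18 to Lac10 all 43 mitosis genes were lower, with a median of -1.04, and 21 fell adjusted over the list alone, with Ccnb2 at -1.65 and Mki67 at -1.64 (adjusted p = 9.82e-31, and adjusted p = 0.491 with an estimated correlation). That step had 449 genes at an unadjusted p under 0.05, 0 with array weights, 1 without mutant Lac10 replicate 1 and 29 without the 7 arrays of lower correlation, which leave 1 mutant Lac10 array, replicate 3, assumed to vary like the other groups. The mitosis median of that step was -0.62 with housekeeping centring.

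In virgins, 4 genes were higher in mutants and none lower. Cyp3a57, a cytochrome P450 gene, was higher by 2.11 (SE 0.235, adjusted p = 0.00025), against a wild-type mean of 4.67 that lies below the array medians. Pgr was higher by 1.81 (SE 0.32, adjusted p = 0.0464, limma), the microRNA gene Mir1933 by 1.72 (SE 0.29, adjusted p = 0.0347) and the transporter gene Slc35f3 by 1.51 (SE 0.24, adjusted p = 0.0335). For each the 3 mutant arrays lay above all 3 wild-type arrays, as the naming rule requires. Groups did not overlap, in either direction, for 34.1% of all genes in virgins. The next smallest p values, not passing, belonged to Stc2 at 1.25 (adjusted p = 0.0584), 2010310C07Rik at 1.28, Reg3g at 1.65, Chst8 at 1.19, Lonrf1 at 1.35, Nrbp2 at 1.57, Chml at 1.15, Zbtb8a at 1.64, the mTOR inhibitor gene Deptor at 1.54 and Zfp619 at 1.27. Hormone-sensing luminal genes were higher in 11 of 12 cases, with a median of 0.69, of which Pgr rose, and 2 rose adjusted over the list alone (adjusted p = 0.0114, and adjusted p = 0.917 with an estimated correlation). The median of that list was 0.58 without wild-type virgin replicate 2 and 0.45 without mutant virgin replicate 1, where the preset test no longer passed, nor did it without the 3 arrays of lowest correlation (0.69). All 22 luminal epithelium genes were higher as well, with a median of 0.60 that did not pass (adjusted p = 0.0645, and adjusted p = 0.917 with an estimated correlation) but did at 0.45 with housekeeping centring (adjusted p = 0.0329). The luminal medians of the wild-type virgin arrays were 9.06, 7.96 and 8.63, lowest in replicate 2. Pgr did not pass with housekeeping centring.

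Mitosis genes lay lower in mutant virgins in 37 of 43 cases, with a median of -0.27 and Cdk1 at -0.81 (adjusted p = 3.49e-05), as did fibroblast and matrix genes in 21 of 25, with a median of -0.26 and Col1a2 at -0.77 (adjusted p = 3.49e-05). Macrophage and neutrophil genes had a median of -0.34 (adjusted p = 0.000282), skeletal muscle genes of -0.55 (adjusted p = 0.000139), and immediate early and heat shock genes of 0.48 (adjusted p = 0.0036). For these 5 lists the adjusted p = 0.917 with an estimated correlation. Mitosis and fibroblast medians were -0.42 and -0.41 with housekeeping centring, still called. The mitosis median was -0.06 without wild-type virgin replicate 1, and -0.45 and -0.11 without mutant virgin replicates 1 and 3. Without wild-type virgin replicate 1 the fibroblast, macrophage and skeletal muscle medians were -0.59, -0.64 and -0.96, and without mutant virgin replicate 1 the fibroblast and muscle ones were -0.41 and -0.37. Without wild-type virgin replicate 2 the fibroblast, macrophage and skeletal muscle medians were 0.05, 0.10 and 0.08 and none was called, while the immediate early median was 0.74. Without replicate 3 the muscle median was -0.84 and the immediate early median 0.30 and not called, nor was that list called without the 3 arrays of lowest correlation, at 0.48. The median over all genes was 0.20, and 2403 genes had an unadjusted p under 0.05. The count of 4 was 8 (3 higher, 5 lower) and 1 without wild-type virgin replicates 1 and 2, and 1, 2 and 11 without mutant virgin replicates 1, 2 and 3. It was 3067 (2263 higher, 804 lower) without the 3 arrays of lowest correlation, which all belong to other stages, and those 3067 include the 4. The virgin differences are the same in that fit, so the move came with the spread that all groups share. The 4, with none lower, therefore depend on that shared spread. Fitted on the virgin arrays alone it was 714 (374 higher, 340 lower).

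At dp12, where all 6 arrays had a median correlation between 0.96 and 0.966, no gene passed as different between genotypes by limma (184 at an unadjusted p under 0.05, 145 with array weights, 6 when fitted on these arrays alone). Each gene has 1 spread shared by all groups, so the lack of a pass does not show that no gene differed. The coat colour gene nonagouti was at 8.79 ± 0.05 (SD, n = 3) in mutants and 4.84 ± 0.09 in wild type. Its SE was 0.90 with all arrays, and 0.37 without the 2 arrays of discordant nonagouti, which belong to other stages. The gene of smallest p was Pi15, a secreted protease inhibitor gene, at -1.40 (SE 0.30), followed by nonagouti at 3.95 (SE 0.90), Gm13546 at 0.95, Dhrs9 at -1.63, Ulbp1 at 1.20, Apln at 1.75, Fam171b at -0.87, Slc25a34 at 0.82, Gpa33 at 0.60 and Mir139 at 0.75, each with an adjusted p of 1. As lists, fibroblast and matrix genes were lower in mutants in all 25 cases, with a median of -0.64 and Fn1, the fibronectin gene, at -1.14 (preset adjusted p = 1.61e-26, adjusted p = 0.246 with an estimated correlation). Endothelial genes were lower in 18 of 19 cases, with a median of -0.22 (adjusted p = 0.021, and adjusted p = 0.991 with an estimated correlation), and hormone-sensing luminal genes in 9 of 12, with a median of -0.30 (adjusted p = 0.00869, and adjusted p = 0.41 with an estimated correlation). The endothelial median was -0.33 without wild-type dp12 replicate 1 or 2 or mutant dp12 replicate 1, and not called at -0.10 and -0.14 without wild-type replicate 3 and mutant replicate 2. The hormone-sensing median was -0.17 without wild-type dp12 replicate 3 and -0.21, not called, without mutant dp12 replicate 1. Brown adipocyte and circadian clock genes were called as lower too, with medians of -0.10 and -0.19 (adjusted p = 0.0422 and 0.021, and adjusted p = 0.41 and 0.824 with an estimated correlation). The brown adipocyte median was -0.15 without wild-type dp12 replicate 3 and, not called, -0.05, -0.08 and -0.04 without wild-type replicate 2 and mutant replicates 1 and 2, and the clock median was -0.19 and not called without wild-type replicate 2 and -0.11 without mutant replicate 2. With housekeeping centring the endothelial, hormone-sensing and brown adipocyte lists were not called, at -0.31, -0.40 and -0.20, and the clock median was -0.29. Replication genes were higher in 51 of 57 cases, with a median of 0.25 and Fen1 at 0.77 (adjusted p = 3.47e-14), repair genes in 29 of 36 with a median of 0.14 and Exo1 at 0.70 (adjusted p = 1.07e-05), lipid synthesis genes in 33 of 39 with a median of 0.22 (adjusted p = 3.97e-07), and milk genes in 25 of 30 with a median of 0.21 and Wap at 1.25 (adjusted p = 0.000307). For these 4 lists the adjusted p = 0.629 with an estimated correlation. Without mutant dp12 replicate 3 the repair median was 0.04 and not called, and the replication median 0.17. The replication and repair medians were 0.38 and 0.21 without wild-type dp12 replicate 1 and 0.15 and 0.09 without replicate 2, the repair median was 0.24 without mutant dp12 replicate 1, and the lipid median 0.09 without wild-type dp12 replicate 3. Mitosis genes had a median of 0.08 and did not pass (adjusted p = 0.0696); with housekeeping centring that median was -0.02, while the test passed upwards (adjusted p = 0.00914). That centring put the replication, repair, lipid and milk medians at 0.16, 0.04, 0.12 and 0.11, still called.

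At dp18 no gene differed between genotypes by limma either, with 100 at an unadjusted p under 0.05 and 0 with array weights. The smallest p values belonged to the somatostatin receptor gene Sstr5 at 0.62, Fut2 at -0.75, Prss48 at -0.72, Ccnq at 1.13, the interferon-induced gene Ifit3 at 0.86, Tmem202 at 0.89, Gm19600 at -0.90, nonagouti at 2.68, Nnat at -1.20 and Mdfi at -0.84, each with an adjusted p of 1. Ccnq and Tmem202 have a probe set of opposite sign. All 28 T and B lymphocyte genes were higher in mutants, with a median of 0.76 and the immunoglobulin gene Ighm at 1.90 (preset adjusted p = 3.38e-19, adjusted p = 0.476 with an estimated correlation), and so were all 23 interferon-stimulated genes, with a median of 0.52 and Ifit1 at 1.04 (adjusted p = 1.15e-11, and adjusted p = 0.551 with an estimated correlation). Without the array labelled mutant dp18 replicate 2 these medians were 0.40 and 0.25, and the interferon median was 0.91 and 0.24 without mutant dp18 replicates 1 and 3 and 0.25 without wild-type dp18 replicate 1. Luminal epithelium genes were lower in 20 of 22 cases, with a median of -0.68 and the claudin gene Cldn4 at -1.31 (adjusted p = 5.81e-10, and adjusted p = 0.551 with an estimated correlation), and at -0.19 they were not called without the array labelled mutant dp18 replicate 2, and they were at -1.11 without replicate 3. With housekeeping centring the replication and mitosis medians were -0.07 and -0.06. Without that centring these genes had medians of 0.19 and 0.20 (adjusted p = 8.63e-07 and 0.000606, and adjusted p = 0.781 and 0.862 with an estimated correlation). They were -0.05 and -0.11 without wild-type dp18 replicate 1, and the mitosis median was -0.02 without the array labelled mutant dp18 replicate 2, none of them called there. The replication median was 0.07 without that array and 0.09 without mutant replicate 3, and the replication and mitosis medians were 0.39 and 0.49 without wild-type replicate 3 and 0.45 and 0.47 without mutant replicate 1. Endothelial genes were at 0.30 (adjusted p = 0.0274, and adjusted p = 0.862 with an estimated correlation), and at -0.35, called the other way, without the array labelled mutant dp18 replicate 2; they were not called without wild-type dp18 replicates 1 and 3, at -0.10 and 0.41, and lay at 0.55, 0.73 and 0.52 without wild-type replicate 2 and mutant replicates 1 and 3. Macrophage and neutrophil genes were higher in 23 of 25 cases, with a median of 0.41 (adjusted p = 8.79e-07, and adjusted p = 0.556 with an estimated correlation), which was 0.08 without wild-type dp18 replicate 1, 0.94 without mutant dp18 replicate 1 and 0.07 without the array labelled mutant dp18 replicate 2. Without the 3 arrays of lowest correlation the mitosis and endothelial medians were 0.12 and 0.33, neither called. With housekeeping centring the lymphocyte, interferon, macrophage and endothelial medians were 0.50, 0.26, 0.15 and 0.04, still called.

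At Lac10, 36 genes were lower in mutants and none higher. The largest falls were in the dopamine receptor gene Drd4 at -3.14 (SE 0.48, adjusted p = 0.012, limma), Chrdl2 at -2.98 and the lysolipid transporter gene Mfsd2a at -2.85. Next came Gldc at -2.58, Gdap10 at -2.42 and the aspartate aminotransferase gene Got1 at -2.37. Fen1 was at -2.36 on its brightest probe set, with another of opposite sign. Lpo was at -2.27, the transferrin receptor gene Tfrc at -2.26 and Fkbp11 at -2.22. For each, all 3 mutant arrays lay below the wild-type arrays, as the naming rule requires. Groups did not overlap, in either direction, for 15.7% of all genes at Lac10. Lipid synthesis genes were lower in 38 of 39 cases, with a median of -1.29. Srebf1, the regulator of fatty acid synthesis, fell by 1.85 (SE 0.32, adjusted p = 0.0299), and the sterol synthesis genes Lss and Mvd were at -1.51 and -1.41, both past the threshold. Adjusted over the list alone 30 fell (preset adjusted p = 1.14e-16, adjusted p = 0.778 with an estimated correlation, and 0.0143 by fry). Of 30 milk and secretory genes Stat5a, the transcription factor of prolactin signalling, fell by 1.61 (SE 0.33, adjusted p = 0.0455), and 7 fell adjusted over the list alone, with a median of -0.89 (adjusted p = 0.00403). The casein genes Csn2 and Csn1s1 were not lower, with means of 13.05 and 12.66 in mutants and 12.92 and 12.49 in wild type. Both lie near the top of the range. The means of Wap were 10.80 ± 1.07 (SD, n = 3) in mutants and 11.76 ± 0.47 in wild type. Those of Lalba were 11.72 ± 0.90 and 12.17 ± 0.83. For both genes the mutant and wild-type arrays overlapped, so no fall is set apart from the spread. Oxidative phosphorylation genes had a median of -0.59 and 22 fell adjusted over the list alone (adjusted p = 7.5e-08). Luminal epithelium genes had a median of -1.03, with Cldn8 at -1.66 and 7 falling adjusted over the list alone (adjusted p = 0.000497). For these 3 lists too the adjusted p = 0.778 with an estimated correlation. With housekeeping centring, which raised every difference at Lac10 by 0.46, the lipid, milk, oxidative phosphorylation and luminal medians were -0.82, -0.43, -0.125 and -0.57, all still called. That shift rests largely on mutant Lac10 replicate 2, the array of lowest correlation. Its housekeeping median was 8.01, against 8.75 and 9.05 in the other mutant arrays and 9.01 to 9.15 in wild type.

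**Figure D3:**
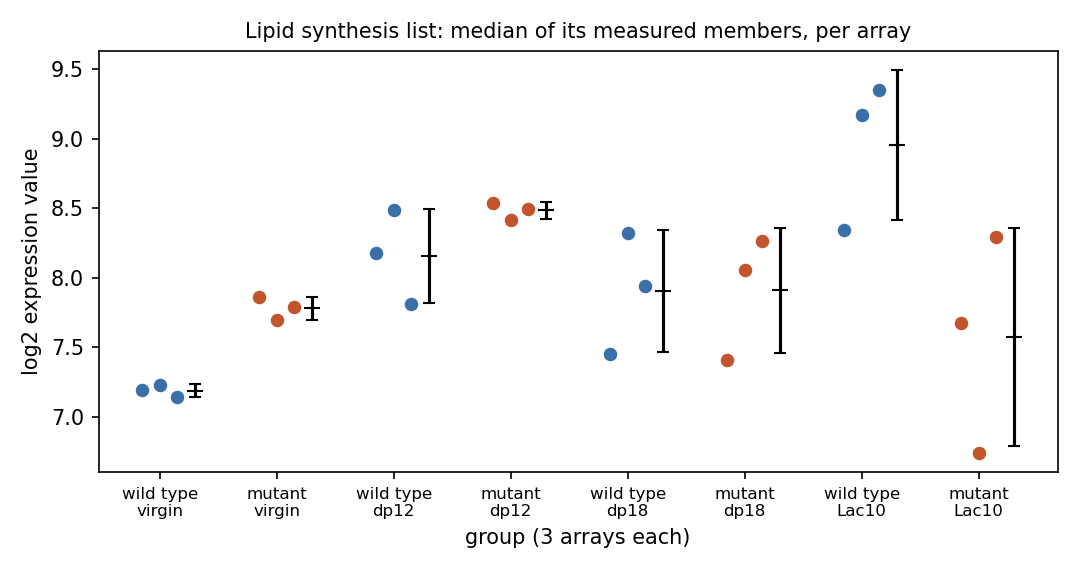
Median log2 expression value of the 39 measured lipid synthesis genes on each array (vertical axis), 3 points per group, with the group mean ± SD in black beside them. At Lac10 the 3 wild-type arrays lie at 8.34, 9.17 and 9.35 and the 3 mutant arrays at 7.68, 6.74 and 8.30; the lowest, mutant replicate 2, is the array of lowest correlation with the others.

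The Lac10 arrays were uneven. Mutant Lac10 replicate 2 had the lowest correlation of all arrays, and without it the milk, oxidative phosphorylation and luminal epithelium medians were -0.54, -0.33 and -0.40, the last not called. The luminal median was -0.89 and not called without mutant replicate 3, and without mutant replicate 1 the luminal and milk medians were -1.93 and -0.58. Of the lists of other cells 3 were called as higher, T and B lymphocyte genes with a median of 0.33 (adjusted p = 0.00024), skeletal muscle genes at 0.26 (adjusted p = 0.000506) and adipocyte genes at 0.12 (adjusted p = 0.0234). With an estimated correlation the first 2 had an adjusted p = 0.778 and adipocyte genes an adjusted p = 0.847. The lymphocyte, muscle and adipocyte medians were 0.79, 0.72 and 0.58 with housekeeping centring, the last not called. Macrophage and neutrophil genes had a median of -0.54, and brown adipocyte, nerve and endothelial genes medians of -0.44, -0.23 and -0.19, which turned to 0.03, 0.23 and 0.28 with housekeeping centring; these 4 were not called, and the endothelial test pointed up, against its median. The lymphocyte and adipocyte medians were 0.04 and -0.17 without mutant replicate 3 and the adipocyte median 0.02 without the array labelled wild-type Lac10 replicate 1, none called. The lymphocyte median was 0.53 without that last array, and both were 0.52 and 0.59 without mutant replicate 1, 0.18 and 0.19 without wild-type replicate 2 and 0.20 and 0.07 without replicate 3; the muscle median was 0.50 without mutant replicate 2. Without the 3 arrays of lowest correlation adipocyte genes were at 0.12 and not called, and without the 7 arrays under 0.94 milk genes were at -0.11 and not called, where replicate 3 was the single mutant Lac10 array left and was assumed to vary like the other groups. The median over all genes was -0.19, and 2676 genes had an unadjusted p under 0.05. The count of 36 was 0 without wild-type Lac10 replicate 2 or 3 or mutant Lac10 replicate 2, 292 without mutant replicate 1, 1390 without mutant replicate 3 and 296 without the array labelled wild-type Lac10 replicate 1, of which 21, 260 and 6 were higher. With array weights it was 3306, of which 981 were higher. Without the 3 arrays of lowest correlation it was 0, without the 7 arrays, again with that single mutant array, it was 35, of which 31 were higher and 4 lower, and with housekeeping centring 10, of which 2 were higher and 8 lower.

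Averaged over the 4 stages, no gene differed between genotypes by limma (smallest adjusted p = 0.104, 458 genes at an unadjusted p under 0.05, 119 with array weights). The smallest p belonged to nonagouti, the coat colour gene that encodes agouti signalling protein, at 2.70 (SE 0.45), followed by Duoxa1 at -0.84, Ifi209, higher 2.82-fold, Cyp3a57 at 0.57, Klk1b11 at -0.50, Reg3g at 0.75, Tfb2m at -0.58, Duox1 at -0.80, Atp13a4 at -1.14 and Mapk4 at -0.62. Tfb2m has a probe set of opposite sign. As nonagouti differed by label in 22 of 24 arrays, the 2 exceptions were followed up: it was at 9.18 in the array labelled wild-type Lac10 replicate 1, where the other 11 wild-type arrays lay between 4.76 and 5.19, and at 4.96 in the array labelled mutant dp18 replicate 2, where the other 11 mutant arrays lay between 6.54 and 8.95. A coat colour gene that followed the label in a mixed strain leaves open that strain background differed with genotype. The 2 cannot be told apart in any genotype comparison here. All 28 T and B lymphocyte genes were higher on average, with a median of 0.37 (adjusted p = 9.12e-12), and fibroblast and matrix genes were lower in 24 of 25 cases, with a median of -0.21 (adjusted p = 9.37e-08), both with an adjusted p = 0.879 with an estimated correlation. The fibroblast median was -0.34 and -0.13 without wild-type virgin replicates 1 and 2. The count was 1 without the array labelled mutant dp18 replicate 2 and 6 without the array labelled wild-type Lac10 replicate 1. The SE of nonagouti on average, from a spread shared by all groups, was 0.45 with all arrays and 0.20 without those 2.

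**Figure D4:**
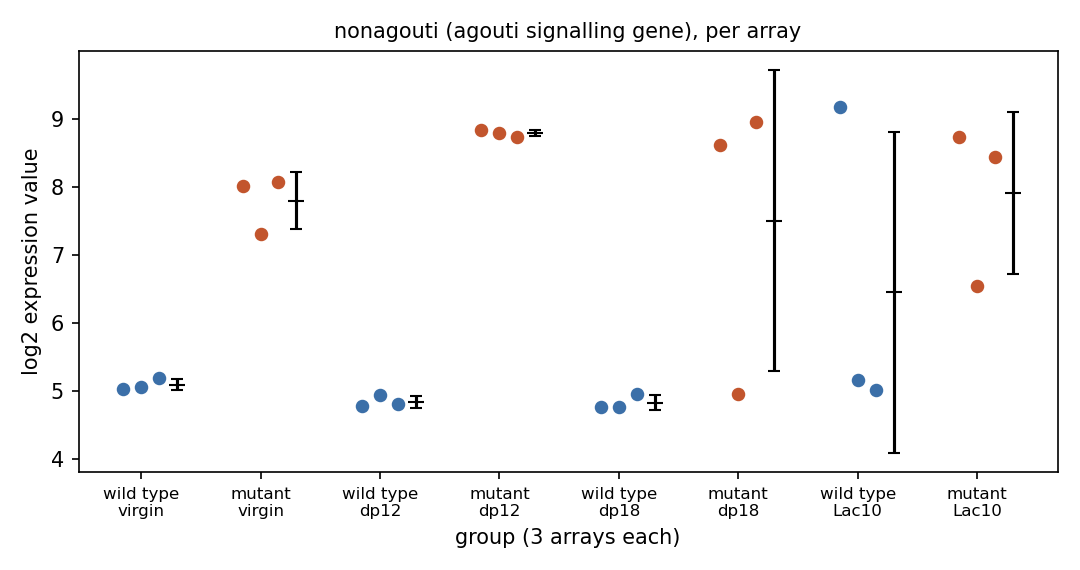
Log2 expression value of nonagouti on each array (vertical axis), 3 points per group, with the group mean ± SD in black beside them. One array labelled wild-type Lac10 lies at 9.18, above every mutant array, and one labelled mutant dp18 lies at 4.96 among wild-type levels.

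Whether the genotype difference changed with stage was tested directly. Cyp3a57 alone passed (adjusted p = 0.0469, limma moderated F; 1892 genes at an unadjusted p under 0.05), with means of 6.78 in mutant and 4.67 in wild-type virgins and between 3.26 and 3.89 in all later groups, all below the array medians except mutant virgins. The next smallest p values belonged to Mir1933 (adjusted p = 0.0794), Drd4, Mfsd2a, Tfrc and Fos (adjusted p = 0.138), Apln (0.164), and Fkbp11, Slc5a6 and Slc35f3 (0.2). By step, Cyp3a57 fell by 2.21 more in mutants between virgin and dp12 (SE 0.33, adjusted p = 0.0252), where 907 genes had an unadjusted p under 0.05. Hormone-sensing luminal genes differed in that step by a median of -0.90, lower in 10 of 12 cases (preset adjusted p = 0.000958, adjusted p = 0.352 with an estimated correlation, 0.0251 by fry). Between dp12 and dp18 no gene differed by genotype in limma (63 at an unadjusted p under 0.05), while fibroblast genes had a median of 0.61 (adjusted p = 1.73e-16, and adjusted p = 0.447 with an estimated correlation), 0.40 without wild-type dp18 replicate 1 and 0.38 without the array labelled mutant dp18 replicate 2. Between dp18 and Lac10 none did either (954), while lipid synthesis genes had a median of -1.53, lower in 38 of 39 cases, and 26 fell adjusted over the list alone (adjusted p = 2.43e-18, and adjusted p = 0.76 with an estimated correlation; median -0.80 and still called with housekeeping centring). The count of 1 for all stages was 141 without mutant Lac10 replicate 3, 36 without the array labelled wild-type Lac10 replicate 1, 3 without wild-type dp18 replicate 1, 2 without wild-type virgin replicate 1 or mutant dp18 replicate 1, 1 without mutant virgin replicate 2 and 0 without any other array.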

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

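The tests of array quality, of the array labelled wild-type Lac10 replicate 1 and of luminal share, and both tests on nonagouti, were chosen after the result was seen; the tests on the 901 genes and the splits of the samples were not.

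The genotype difference of Cyp3a57 changed with stage (adjusted p = 0.0469 by the moderated F test, limma) and in the step from V to dp12 (adjusted p = 0.0252). Between genotypes, 8, 13 and 13 of the 27 lists differed in the steps V to dp12, dp12 to dp18 and dp18 to Lac10 with the preset correlation, and 0 with an estimated one. Among 9522 probe sets with several or no symbols, which no comparison of named genes uses, 238 changed with genotype in virgins (235 higher, 3 lower), 24 at Lac10 (all lower), 69 from V to dp12 in wild type and 35 in mutants.

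The 36 genes lower in mutants at Lac10 had a median difference of -1.65, with a median single-gene SE of 0.32. They were chosen for passing in this comparison, which favours large differences. The array labelled wild-type Lac10 replicate 1 is argued against as their source, since all 36 passed without it and the array labelled mutant dp18 replicate 2 (median -1.90). Array quality stays open. With it as a covariate the median was -1.33, and without the 3 arrays of lowest correlation -1.39. The median single-gene SEs were 0.30 and 0.31, and 0 of the 36 passed the threshold either way. In both fits 9 of the 36 had an unadjusted p (limma) at or below 0.000114, the highest among the 36 before. Of all genes 13 and 12 did. The mutant arrays lay at -1.58, -2.29 and -1.15 against the wild-type mean. Quality here is an array's median correlation with the other 23, not a technical measure. It followed the main axis of variation among arrays (first principal component, 45.1% of the variance) with a correlation of 0.964. The covariate can therefore take out biological differences too. A lower share of luminal epithelium cannot be told apart from the other explanations: that list had a median of -1.03 (SE 0.105 over its members, not over arrays; -0.40 and not called without mutant Lac10 replicate 2), none of its members is among the 36, and the 15 pairs of lists of other cell types had SEs from 0.303 to 0.599, too imprecise to show whether these moved alike (smallest adjusted p = 0.773). The stage of the mutant arrays is a further open point, not tested for the 36 genes. On the stage genes described below, mutant Lac10 replicate 1 lay at 0.05 between dp18 (0) and Lac10 (1). Replicate 3 lay at 0.85, and its 36 genes were still at -1.15. The genotype itself, with any strain background that went with its label, stays among the open explanations.

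Nonagouti was at 9.18 in the array labelled wild-type Lac10 replicate 1 and at 4.96 in the array labelled mutant dp18 replicate 2, the first above and the second among the levels of the other genotype. An exchange of these labels may explain both: on 100 genes that part the stages, chosen on 7 other arrays, the first lay at 0.22 and the second at 0.76 between dp18 (0) and Lac10 (1). Held-out dp18 arrays lay between 0.04 and 0.31, and held-out Lac10 arrays at 0.82, 0.85 and 0.98 except mutant Lac10 replicate 1, which lay at 0.05. With each other left out, the first array correlated highest with a mutant dp18 array (0.984, against 0.969 in its own group and 0.981 with wild-type dp18) and the second with a mutant Lac10 array (0.973, against 0.956). An exchange would make the second a wild-type Lac10 array. Its highest correlation with that group was 0.96, the same as with wild-type dp18, which does not favour the genotype side of an exchange. An allele of this coat colour gene segregating in the mixed strain would by itself leave both arrays within their labelled stage. For the first array the test cannot decide, because the held-out stages overlap, which rests on mutant Lac10 replicate 1. The second, at 0.76, lay outside the held-out dp18 arrays, which goes against an allele alone for that array. On the second principal component it lay at -46.24, near wild-type Lac10 replicates 2 and 3 (-45.77 and -40.18). An exchange is not thereby shown. Of the arrays with a colour word in the title, 4 of 6 white, 0 of 3 brown and 1 of 1 golden had a level above 6.

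The 901 genes that rose from V to dp12 in wild type could reflect the lower resemblance of the wild-type virgin arrays. As the whole cause this is argued against: in mutants, whose virgin arrays do not share it, these genes lay 0.77 above all genes (SE 0.12; 0.92 in wild type), 860 of them higher. For the 607 not called in mutants the value was 0.57 (SE 0.09; 0.88 in wild type), above the bound of 0.44 set beforehand by more than its SE, which argues against it as the whole cause here too. A partial effect of quality and a change with pregnancy stay open.

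With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real counts and the highest of the other splits were 4 and 0 for genotype in virgins, 0 and 0 at dp12, 0 and 2477 at dp18 and 36 and 192 at Lac10. For the steps they were 983 and 0, 0 and 1, and 0 and 1 in wild type, and 677 and 0, 0 and 0, and 0 and 5751 in mutants. As many genes as the real split came from 1, 10, 10 and 2 splits for genotype and from 1, 10 and 10 for the steps of each genotype, the real one included; a real count of 0 is reached by any split. The 2477, 192 and 5751 point to a structure of the samples: the first put wild-type dp18 replicate 1 with mutant dp18 replicates 1 and 2, the second mutant Lac10 replicates 1 and 2 with the array labelled wild-type Lac10 replicate 1, and the last mutant Lac10 replicates 1 and 2 with mutant dp18 replicate 1. Of 100 relabelings within stages, 21 gave at least the 1 gene of the test by stage (highest 125), so chance was not excluded for it. For the average, with 0 genes by limma (458 at an unadjusted p under 0.05, 119 with array weights), all 100 give as many by construction, which decides nothing. The highest counts, 5367 for the average, again point to a structure of the samples.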

How the results depend on the processing

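The settings that leave out 2, 3 or 7 arrays, the quality covariate and the 22 arrays without covariate were chosen after seeing the data. The cause of the changes below was not tested except where fewer arrays or genes were used. Where the arrays left out belong to groups other than those compared, the differences stay the same. A count then moves only with the spread that all groups share. The mean of all probe sets, or every probe set alone, moved no count by over 1.5 times. Without a filter on dim genes the Lac10 count was 6, against 36. With genes above the median gene it was 81 (2 higher, 79 lower), with 0 for virgins, 1 on average and 0 by stage. Centred on array medians, the counts were 1 for virgins, 7 at Lac10, 545 for wild type from V to dp12 and 0 by stage. Centred on the housekeeping list they were 10 at Lac10 (2 higher, 8 lower), 131 for wild type (91 and 40) and 1623 for mutants (272 and 1351) from V to dp12, and 0 by stage. With a variance trend the mutant step from dp12 to dp18 gave 5 and the test by stage 0.

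Array weights gave 5573 (4314 higher, 1259 lower), 145 and 3306 (981 and 2325) genes for genotype at V, dp12 and Lac10, 119 on average and 5990 by stage, 9731, 2751 and 3898 for the wild-type steps and 4104 and 1 for the first mutant steps. The arrays of the compared groups alone gave 714 (374 higher, 340 lower), 6 and 0 at V, dp12 and Lac10, and 5964 and 2771 from V to dp12 in wild type and mutants. With body weight as a covariate virgins gave 647 (397 higher, 250 lower), Lac10 1613 (469 and 1144) and the test by stage 669; the same 22 arrays without it gave 767 (494 higher, 273 lower), 891 (197 and 694) and 466, so most of the move came with the arrays. Without the 3 arrays of lowest correlation the counts were 3067 in virgins (2263 higher, 804 lower), 0 at Lac10, 810 by stage, 6271 in wild type from V to dp12 (all 983 among them), 1605 in mutants (all 677) and 3 in mutants from dp12 to dp18. Without 7 arrays the mutant steps gave 2516, 4 and 29, and Lac10 35 (31 higher, 4 lower), of which 1 was among the 36. The 29 and the 35 rest on 1 mutant Lac10 array, replicate 3, assumed to vary like the other groups; virgins, wild type from V to dp12, the average and the test by stage have no value there. The quality covariate gave 7 in virgins, 0 at Lac10, 1819 and 8 in the first mutant steps and 2 by stage. Without the 2 arrays of discordant nonagouti the genotype counts were 2 (1 of them, Cyp3a57, among the 4 virgin calls), 1, 1 and 269 (all 36 among them), 8 on average and 34 by stage, and 149 for wild type from dp18 to Lac10. The other virgin call, the single calls at dp12 and dp18 and 1 call each at Lac10 and on average are nonagouti, which was used to choose the arrays. At dp18, at Lac10 and on average these are circular. In virgins and at dp12 no array was left out, and the nonagouti differences stayed at 2.71 and 3.95. Their SE fell from 0.90 to 0.37, so the passes there rest on a shared spread that the choice lowered.

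Leaving out each array in turn gave 1 to 11 genes in virgins, 0 at dp12 and dp18, 0 to 1390 at Lac10, 0 to 6 on average and 0 to 141 by stage. The steps ranged from 0 to 904, 0 to 1 and 0 to 148 in wild type and from 262 to 591, 0 to 25 and 0 to 1 in mutants. A group left with 2 arrays shares the spread of all groups. The wild-type number as a replicate block gave 781 genes from V to dp12 on the 12 wild-type arrays, against 1467 without the block, and 0 in the later steps with and without it. Same-numbered arrays deviated with correlations from -0.387 to 0.31 (median 0.027; other numbers -0.007), and 6 of 12 correlated best with their own number, so the arrays share only a number.

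Of 52 list calls for genotype, all 52 were lost with an estimated correlation and 49 by fry. Centring on housekeeping genes kept 47, a weak check because it shifts a list and all other genes alike. With 1 array left out, 465 of the calls were kept, 61 lost and 2 reversed. The reversed ones were endothelium (-0.35, with a range up to 0.73 over the arrays left out) and ribosomal protein (-0.04, within a range from -0.215 to -0.024) at dp18 without mutant dp18 replicate 2, and both also without the 2 arrays of discordant nonagouti. For ribosomal protein only the direction of the test turned, while the median stayed negative. Without those 2 arrays it was not called (adjusted p = 0.921 by camera), whereas endothelium was called as lower (adjusted p = 0.00941). Of 115 list calls in the steps and their genotype differences, housekeeping centring kept 96 and lost 19. For lists of the steps with 1 array left out, an alternative chosen after seeing the data, the test turned direction, with no call, for lipid synthesis (-0.59 to -0.014), oxidative phosphorylation (-0.43 to -0.018) and unfolded protein response (-0.48 to 0.14) from dp18 to Lac10 in mutants without mutant Lac10 replicate 2. In the genotype difference of a step it turned for skeletal muscle from V to dp12 (-0.14 to 0.75, without wild-type virgin replicate 2) and endothelium from dp12 to dp18 (-0.12 to 0.94, without mutant dp18 replicate 2). Signal near the floor limits dim genes such as Cyp3a57.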

Other observations

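The tests without the 2 arrays of discordant nonagouti were chosen after the result was seen, and so were the genes named here. Without them, in wild type from dp18 to Lac10, Csn1s2b, a casein gene, rose by 5.04 (SE 0.71, adjusted p = 0.0011, limma), the calcium pump gene Atp2b2 by 4.08, Egf by 3.96 and Acacb, of fatty acid metabolism, by 3.23. The mucin gene Muc4 was at -3.80 and the claudin gene Cldn1 at -3.40 in that step, both past the threshold. In all, 149 genes changed, 133 higher and 16 lower, where none passed with the 2 arrays kept (1219 at an unadjusted p under 0.05, 3898 with array weights). At Lac10, 269 genes then differed by genotype, 9 higher and 260 lower, among them the sterol regulator gene Insig1 at -3.16, the corticotropin-releasing hormone receptor gene Crhr1 at -3.05 (adjusted p = 7.16e-07) and Gsdmc at -3.36. On average 8 genes passed, including the hydrogen peroxide generating oxidase gene Duox1 at -0.93 and its maturation factor Duoxa1 at -0.92; nonagouti, at 3.36, was used to choose the arrays and its call is circular.

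Csn2, the beta-casein gene, was high at every stage, with means of 12.05 in wild-type and 11.69 in mutant virgins and between 12.72 and 13.05 in the later groups, near the top of the range of the arrays. Adipoq, the adiponectin gene, lay at 7.61 in mutant Lac10 replicate 3, where the highest of the other arrays was at 5.66.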
